A study of Vitis amurensis with 6 samples.

How the data were processed

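RNA was sequenced from leaves of 6 samples of in vitro Vitis amurensis plants, a wild grape of north-east Asia noted for its winter hardiness. Plants of the cold group were held for 2 h at 4 °C, and plants of the control group were kept at 26 °C under the same light, about 100 µmol per square metre and second. Each group holds 3 libraries. Per the labels' protocols, plants of uniform growth were used and libraries were built with an Illumina TruSeq RNA kit from total RNA. Nothing in the labels says whether the libraries of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may in part be technical. The labels do not state the hour of day at which either group was sampled. The control group is labelled with 0 h of cold, which does not tell whether it was sampled before or alongside the cold group. Effects of the 2 h that passed and of moving the plants therefore cannot be told apart from those of temperature.

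The values analysed are FPKM, fragments or reads per kilobase of gene scaled to library size, which the authors deposited as one table of 31845 gene identifiers by 6 libraries. Per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq and DESeq2 were used, named without versions or roles. The genome build and annotation behind the identifiers, the counting mode and the strand setting are not given in the sources used here. No library was pooled, and every column was matched to a sample by its title. No column was left unused.

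The deposited FPKM values kept the trace of whole reads. Within each gene the values of the 6 libraries were whole multiples of one step, and the ratio of the steps between libraries was the same for every gene. The commonest ratio of low values (under 2 FPKM) gave the relative depths, and the scale that made the inverse of the steps whole gave the library totals and a length in bases for each gene. Within 0.001 reads, whole counts were found for 25054 of the 25054 genes above 0 in any library, of which 20133 had reads in all 6, and 6791 genes were at 0 in all libraries. The implied totals were 16657708, 16437001 and 16563238 reads in control libraries 1, 2 and 3, and 18773557, 19468504 and 21217704 reads in cold libraries 1, 2 and 3. The recovered reads summed to between 99.4% and 99.6% of these totals. Where all counts of a gene share a common divisor, the smallest whole counts were taken. A gene read in few libraries can come out whole by chance; of 500 genes read in all 6 libraries whose values were shifted at random, 0 did. In data simulated with the same totals and lengths, 6 of 6 totals were found, and 99.1% of 18046 genes with 10 or more reads in every library had all their counts recovered exactly, as had 98.9% of all genes with reads. The recovered reads served for depth, detection, the floor of 3 reads and an alternative fit; the main test used the FPKM values as deposited. Intervals and floors cover counting error only.

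Genes with a mean of at least 1 FPKM over all 6 libraries entered the test, which left 17155. Cold was compared with control by limma-trend on log2(FPKM + 1), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, two-sided. Fold changes are on this log2(FPKM + 1) scale, which understates the change of low genes. On counts simulated for the real genes with 50 genes changed at each of 4 sizes, the cold against control fit on 17155 genes recovered 29 of 50 genes changed 1.5-fold, 45 of 50 changed 2-fold and 50 of 50 changed 4-fold and 8-fold, and called 8 of 16955 unchanged genes. The simulation gave every gene the same spread between libraries (dispersion 0.0078) and no variation shared between genes. Recovery among genes that vary more was not measured. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.

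The files do not pair the identifiers with gene names, and no annotation of them was used here. Gene lists by function and cell type, fixed by annotated name before the data were examined, therefore had no members and were not tested, and no gene is named by function. By the rule fixed for that case, the genes given by identifier are the 2 with the largest rise and the 2 with the largest fall among genes past the threshold whose groups do not overlap. The identifiers of this grape gene set carry a 2-digit chromosome field, with 00 for sequence not placed on a chromosome, then a scaffold field and a running gene number. These fields were read from the identifiers and were not checked against a genome. Genes were called consecutive when they followed each other in this numbering among the tested genes of a scaffold field. The number of consecutive pairs was compared with 10000 random placements of the called genes within their chromosome fields. Shares per chromosome field were compared by two-sided Fisher's exact tests, adjusted over 40 tests. Groupings by size, detection, chromosome field and consecutive identifiers were chosen after the data were examined.

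Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, 3 other scalings between libraries, variance models without trend or with robust estimation, library weights, the replicate number as a block, and leaving out each library in turn. Alternatives added after seeing the data were limma-voom on the recovered reads, a fit without 97 genes that varied strongly within both groups, and a fit with the level of these genes as a covariate. Added in the same way were other read limits and left-out libraries for genes read in cold only, the settings for consecutive identifiers and chromosome field 16, other limits for the genes that varied, and the shares of the most abundant genes without 64 of those. Each pair of libraries differed by more than sampling noise; the closest pair, cold libraries 1 and 2, had a chi-square of 12.0 per degree of freedom.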

Results

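Transcript levels were measured by RNA sequencing in leaves of in vitro Vitis amurensis plants, 3 libraries from plants kept at 26 °C and 3 from plants moved to 4 °C for 2 h. The comparison addresses which genes respond early when this cold-hardy grape is chilled. Library totals ran from 16437001 to 21217704 reads, and each of the 3 cold libraries was deeper than each control library. Of 31845 gene identifiers, 25054 were above 0 in at least 1 library. The first principal component of log2(FPKM + 1) carried 72.8% of the variance and separated cold from control. Cold libraries 1, 2 and 3 lay at 54.7, 51.1 and 39.3 on it and the control libraries between -50.4 and -44.9. The second component, with 14.2% of the variance, set control library 1 (39.1) apart from control libraries 2 and 3 (-16.6 and -22.7).

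The leaf transcriptome differed broadly between plants held for 2 h at 4 °C and plants kept at 26 °C. Of 17155 tested genes, 3606 were higher and 2295 lower after cold, which together is 34.4% of those tested (limma-trend, adjusted p under 0.05). With a size of at least 2-fold, 1133 genes were higher and 523 lower. Large changes were mostly rises: 362 genes rose and 106 fell at least 4-fold, 139 rose and 24 fell at least 8-fold, and 55 rose and 6 fell at least 16-fold. The libraries of the groups did not overlap for 1655 of the 1656 genes changed at least 2-fold, and for 51.4% of all tested genes, where chance gives 10%.

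The balance of small rises and falls depended on scaling. Rises made up 61.1% of all calls with the values as deposited, 49.0% with median-of-ratios scaling and 45.5% with quantile normalization. Among changes of at least 2-fold the shares were 68.4%, 61.0% and 56.2%, so rises outnumbered falls under each scaling at that size. The median change over all tested genes was 0.08 on the log2 scale as deposited and 0.00 after median-of-ratios scaling. Without cold library 2 the calls numbered 2253 higher and 1425 lower, with library weights 3549 genes were lower, and with a filter at a mean of 5 FPKM 684 genes rose at least 2-fold.

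**Figure D1:**
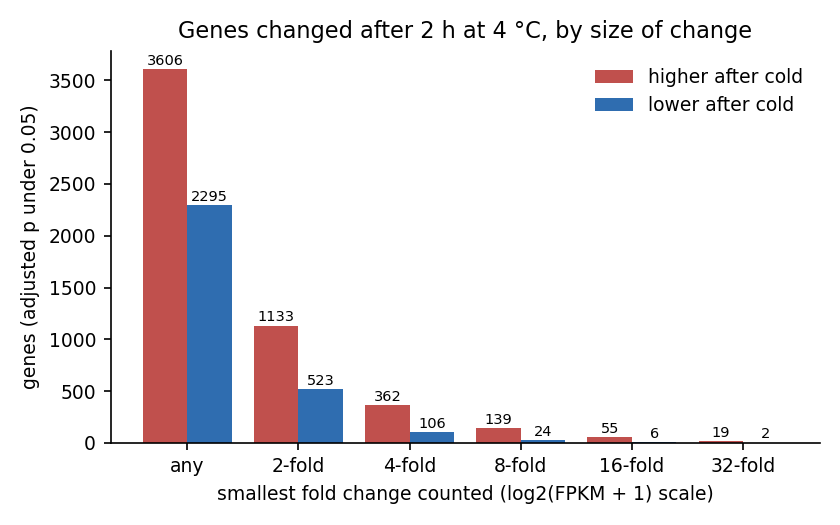
Number of genes with an adjusted p under 0.05 (vertical axis) that were higher (red) or lower (blue) after 2 h at 4 °C, counted from a smallest fold change on the horizontal axis. Rises outnumbered falls in every class, from 3606 against 2295 for any size to 19 against 2 at 32-fold; under median-of-ratios and quantile scaling rises were 49.0% and 45.5% of the calls in the class of any size.

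The genes that rose at least 2-fold were mostly low in warm leaves, with a median of 2.30 FPKM in control and 12.3 FPKM in cold. Those that fell at least 2-fold started from a median of 21.0 FPKM and stood at 5.91 FPKM after cold. Together the risers took 2.46% ± 0.493 (SD, n = 3) of the reads in control and 8.97% ± 0.145 (SD, n = 3) in cold. The fallers took 5.59% ± 0.556 (SD, n = 3) in control and 1.90% ± 0.170 (SD, n = 3) in cold. Genes not called had medians of 8.57 FPKM in control and 8.84 FPKM in cold. These sets were chosen on the same libraries, and the choice itself favours low control levels among risers and high ones among fallers. The levels and shares therefore describe the sets' weight in the transcriptome and are not independent evidence of direction. Among genes with a mean of 1 to 10 FPKM over all libraries 7.58% rose and 2.52% fell at least 2-fold; the shares were 5.50% and 3.40% from 10 to 100 FPKM, and 6.98% and 5.03% above 100 FPKM.

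**Figure D2:**
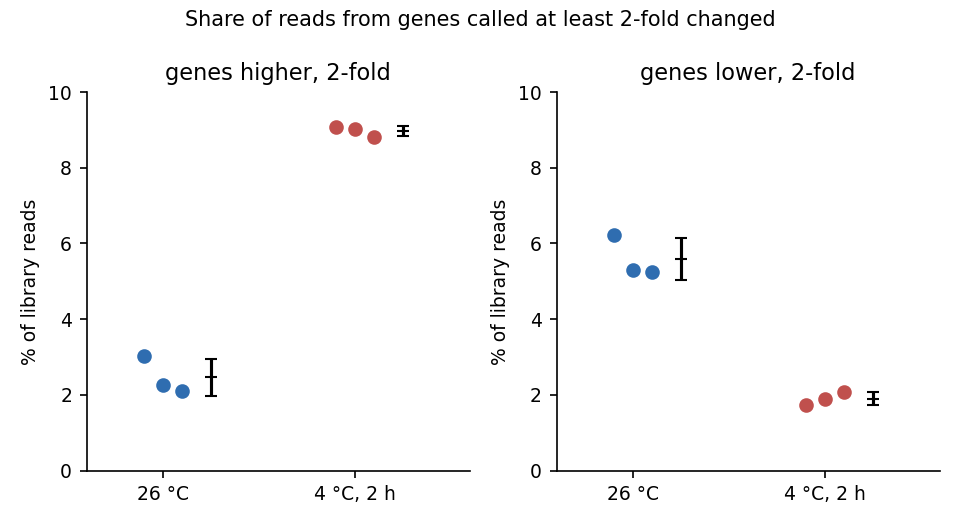
Share of each library's reads, in percent, that came from the 1133 genes called higher (left) and the 523 called lower (right) by at least 2-fold; points are libraries 1 to 3 from left to right, and black marks are the mean with 1 SD. The risers' share lies between 2.11% and 3.03% in control and between 8.81% and 9.08% in cold, and the fallers' share between 5.24% and 6.23% in control and between 1.73% and 2.07% in cold.

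The gene with the largest rise on the log2(FPKM + 1) scale was VIT_211s0016g01810, of chromosome field 11. Its level went from 1.17 ± 0.834 FPKM (SD, n = 3) in control to 263 ± 15.4 FPKM (SD, n = 3) in cold, a log2 change of 6.99 with a standard error of 0.24 (limma-trend, adjusted p = 5.2e-05). All 3 cold libraries lay above all 3 control libraries, with between 8165 and 10352 reads against between 18 and 62. The next was VIT_218s0001g06150, of chromosome field 18, which went from 4.02 ± 1.42 to 541 ± 105 FPKM (SD, n = 3 each), a log2 change of 6.78 with a standard error of 0.24 (limma-trend, adjusted p = 5.7e-05); again all 3 cold libraries were above all 3 control libraries. It stands in a run of 3 consecutive genes that rose, so its own value is uncertain if reads were shared between near-identical copies.

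Both of the largest falls on the log2(FPKM + 1) scale carry chromosome field 17 and scaffold field 0000. In both genes all 3 cold libraries lay below all 3 control libraries. VIT_217s0000g01825 went from 127 ± 151 to 1.23 ± 0.621 FPKM (SD, n = 3 each), a log2 change of -5.20 with a standard error of 0.78 (limma-trend, adjusted p = 0.0037). Its control level was 302 FPKM in library 1 and 35.7 and 44.6 FPKM in libraries 2 and 3, and without control library 1 the log2 change was -4.24. VIT_217s0000g01080 went from 148 ± 119 to 2.74 ± 0.576 FPKM (SD, n = 3 each), a log2 change of -5.05 with a standard error of 0.49 (limma-trend, adjusted p = 0.0009). Its control level was 285 FPKM in library 1 and 79.6 and 79.4 FPKM in libraries 2 and 3, and without control library 1 the log2 change was -4.44. The tested gene that follows it also fell at least 2-fold, so the same uncertainty applies.

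A set of genes went from near silence to clear expression. In 55 genes each control library held at most 3 reads and each cold library at least 30, and 48 of these passed the test; 7 had a mean under 1 FPKM and were not tested. The converse, at most 3 reads in every cold library and at least 30 in every control library, held for 2 genes. Reads were counted at each library's own depth, and each cold library was deeper than each control library, which favours genes read in cold only. Since the rule itself asks for separated groups, passing the test adds little. Of the 55 genes, 12 had no read in any control library. Set against a floor of 3 reads over the pooled control libraries, these were at least 46.5-fold to at least 417-fold higher in cold. The count depends on the read limit: it was 169 with at least 10 reads in each cold library and 16 with at least 100. It was 88 when control library 1 and 90 when cold library 3 was left out.

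More genes were read in cold leaves, and the most abundant genes took a smaller share of their reads. At an equal depth of 16367827 reads, 18647 ± 46.4 genes (SD, n = 3) had 10 or more reads in cold and 18042 ± 131 (SD, n = 3) in control. At each library's own depth, the 10 most abundant genes took 6.09% ± 0.284 (SD, n = 3) of the reads in cold and 7.93% ± 1.22 (SD, n = 3) in control, and the 100 most abundant 18.8% ± 0.808 and 22.0% ± 1.28 (SD, n = 3 each). The groups did not overlap in any of these measures, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 libraries against 3 can give. Without 64 genes that varied within both groups, the 10 most abundant took 5.89% ± 0.0641 in cold and 7.15% ± 0.206 in control (SD, n = 3 each).

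Genes that rose together often carried consecutive identifiers. Of the 1133 risers, 440 (38.8%) stood in runs of 2 or more consecutive tested genes that all rose at least 2-fold. They formed 271 consecutive pairs, where random placement within chromosome fields gave 77.3 on average and 111 at most (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). There were 45 runs of 3 or more risers, with 192 genes, and the longest held 10. The fallers formed 53 pairs against 15.7 on average by chance (one-sided permutation p = 0.0001), with 4 runs of 3 or more. With a filter at a mean of 5 FPKM the risers formed 140 pairs. Genes under the filter were skipped in the numbering, so members of a run need not be neighbours. With no filter on low values the risers formed 264 pairs, counted in this same numbering. That count cannot show whether runs depend on the filter. The filter uses all 6 libraries, so a gene near silence in warm leaves entered only through its level in cold. A run of 4 genes on scaffold field 0088 of chromosome field 03, for example, averaged 0.242 FPKM in control and 69.5 FPKM in cold. The random placements used the same tested genes and do not address this. Consecutive genes can be near-identical copies, and the way in which reads shared between copies were counted is not given in the sources used here, so the values of single members of a run are uncertain.

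The longest runs show how strong these blocks were. On scaffold field 0148 of chromosome field 16, 10 of the 10 genes that passed the filter rose (9 of 10 under quantile normalization), with log2 changes between 1.13 and 3.10, and their summed level went from 7.29 ± 2.39 to 76.1 ± 14.2 FPKM (SD, n = 3 each). These genes averaged 0.729 FPKM in control and 7.61 FPKM in cold, so their level in cold carried them past the filter; with no filter 11 of 31 genes of this scaffold field rose, and with a filter at a mean of 5 FPKM 2 of 2. On scaffold field 0052 of chromosome field 11, 10 consecutive genes rose by log2 changes between 1.62 and 4.11, from a sum of 36.8 ± 0.545 to 241 ± 75.2 FPKM (SD, n = 3 each). On scaffold field 0013 of chromosome field 16, 26 of 74 tested genes rose at least 2-fold. A run of 8 genes there went from a sum of 56.9 ± 43.9 to 1262 ± 188 FPKM (SD, n = 3 each), with log2 changes between 2.71 and 4.81; without control library 1 its control mean was 31.9 FPKM. A run of 8 genes on scaffold field 0025 of chromosome field 02 went from 33.0 ± 13.0 to 263 ± 164 FPKM (SD, n = 3 each), and without cold library 2 its cold mean was 169 FPKM. The longest run of fallers, 6 genes on scaffold field 0003 of chromosome field 10, went from 176 ± 62.3 to 68.8 ± 10.5 FPKM (SD, n = 3 each).

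**Figure D3:**
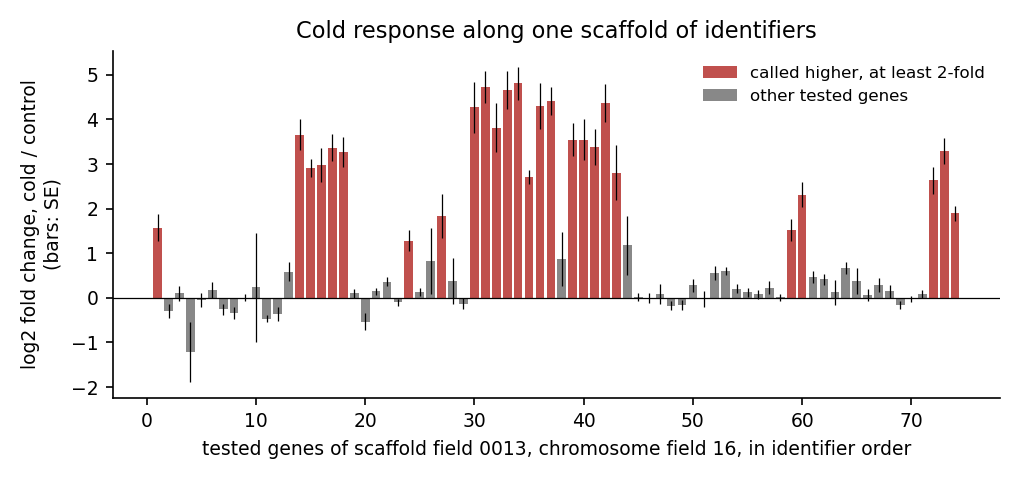
Log2 fold change, cold over control (vertical axis, error bars 1 SE), of the 74 tested genes with chromosome field 16 and scaffold field 0013, in the order of their identifiers (horizontal axis, not to genomic scale). Of the 26 genes called at least 2-fold higher (red), 23 stand in 5 blocks of 2 or more and 3 stand alone; the longest block has 8 members and log2 changes between 2.71 and 4.81.

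Risers were most frequent in chromosome field 16. There 94 of 630 tested genes (14.9%) rose at least 2-fold, against 6.29% of the genes of all other fields (Fisher's exact test, odds ratio 2.61, adjusted p = 2.8e-12 over 40 tests). The 3 scaffold fields of chromosome field 16 with the most risers held 63 of the 94. The rest of the field had 31 risers among 281 genes, against 6.29% in other fields (Fisher's exact test, p = 0.0028). That rest still holds scaffold field 0148, where 10 of 10 tested genes rose, and scaffold field 0100, where 9 of 53 rose. Both carry runs of risers, so the test does not show an excess outside runs. Chromosome field 13 had fewer risers, 4.05% against 6.76% elsewhere (adjusted p = 0.0076), and chromosome field 02 more fallers, 5.56% against 2.95% elsewhere (adjusted p = 0.0076). The other 37 tests did not pass. These tests treat genes as independent, and the members of runs are not.

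**Figure D4:**
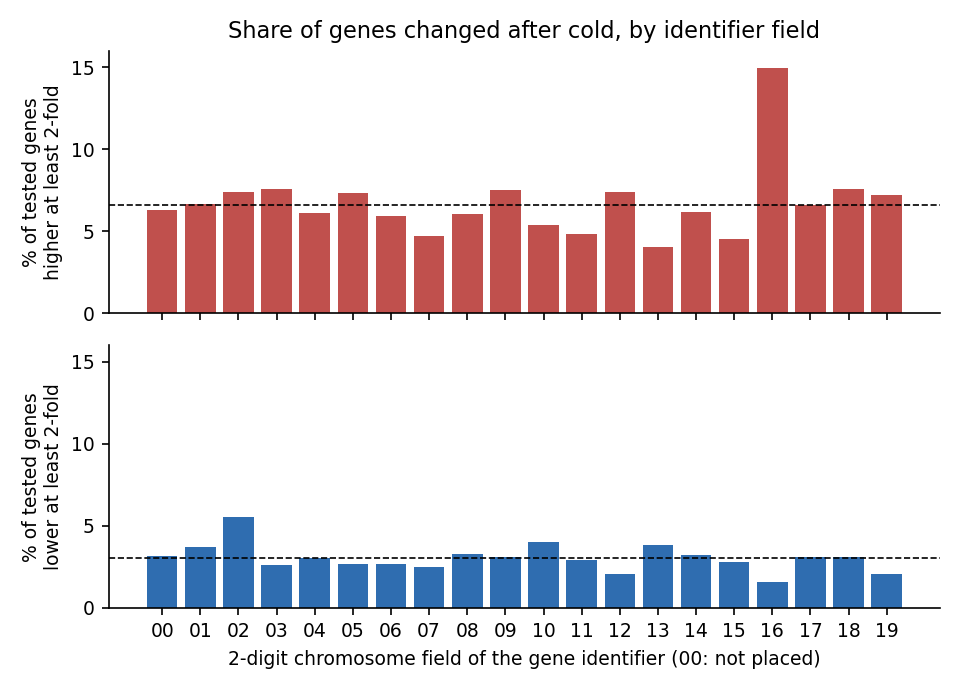
Percent of tested genes that were higher (upper, red) or lower (lower, blue) by at least 2-fold after cold, for each 2-digit chromosome field of the identifiers; dashed lines are the shares over all tested genes. Chromosome field 16 stands at 14.9% for risers, against 6.29% over all other fields.

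The libraries of a group differed in the size of these changes. Among the 1133 risers, cold library 3 was the lowest cold library for 54.5%, and among the 523 fallers it was the highest for 55.6%. Its median deviation from the other cold libraries was -0.18 on the log2 scale for risers and 0.18 for fallers. For the 106 genes that fell at least 4-fold it was the highest cold library in 72.6%, with a median deviation of 0.43. Cold library 1 lay to the other side for fallers: it was the lowest cold library for 54.3% of the 523 and 77.4% of the 106, with median deviations of -0.16 and -0.39, while those of cold library 2 were 0.00 and 0.03. Among the 139 genes that rose at least 8-fold, control library 1 was the highest control library for 67.6%. Control library 1 was the highest control library for 58.5% and the lowest for 31.1% of the 106 genes that fell at least 4-fold. Of the 523 fallers it was the highest for 239 and the lowest for 209, with a median deviation of 0.01. Without control library 1 the counts of at least 2-fold changes were 1251 higher and 588 lower, and without cold library 3 they were 1161 and 542.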

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

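Alternatives on voom and on the genes that vary within both groups, those for genes read in cold only, consecutive pairs and chromosome field 16, and the test over splits were chosen after seeing the data; the others were fixed before the data were examined. All 1656 genes changed at least 2-fold kept their sign in each setting that tested them, and the 4 genes given by identifier kept theirs with an adjusted p of at most 0.031 (limma-voom on recovered reads). Of the 1656, 1642 were still called under median-of-ratios scaling, 1599 under limma-voom, 1574 with the replicate block, 1494 without cold library 1 and 1472 without cold library 2, the fewest of the settings that tested all 1656. Counts of changed genes, consecutive pairs and risers of chromosome field 16 under alternatives lay within 1.5 times the reported count in 114 cases. Of these, pairs with no filter decide nothing. The 6 others follow. The count of genes lower at any size was 3549 with library weights. With the filter at a mean of 5 FPKM (12090 genes tested), risers of at least 2-fold numbered 684. Their consecutive pairs numbered 140, and risers of chromosome field 16 numbered 59. The cause was not tested. Leaving out each library in turn gave 2253 to 4180 genes higher, 1425 to 2746 lower, 1011 to 1251 higher and 450 to 588 lower by at least 2-fold, 225 to 308 consecutive pairs and 82 to 100 risers of chromosome field 16; the low ends for all calls came without cold library 2, and the cause was not tested. With the replicate number as a block (replicate block), 2480 genes were higher and 1627 lower, and the counts at 2-fold or more were 1083 and 500; same-numbered libraries did not deviate together (correlations of deviations from the group means -0.26, -0.13 and -0.28), and 0 of the 3 control libraries correlated best with the cold library of its own number. The gene list tests, their estimated correlation and the rotation test were not run, because the files do not pair identifiers with names, nor were the alternatives meant for a file of counts. Genes read in cold only numbered 62 to 90 with a library left out, since one fewer library has to meet the rule. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 5901 genes and 1656 at 2-fold or more with limma-trend. The highest other split called 0 of either. Other splits gave at most 765 genes at an unadjusted limma-trend p under 0.05, against 7812 in the real one. Each other split mixes cold and control libraries, so the difference between the groups adds to the spread within its sets and lowers its counts. The low counts of the other splits therefore say little about chance. Only 1 of 10 splits gave as many, and the splits are too few for a share under 0.05. The genes that varied within both groups and shared an order numbered 99 with a range limit of 1 and 97 with a pseudocount of 0.1. At this depth and with the same spread for every gene, 45 of 50 simulated 2-fold changes and 29 of 50 of 1.5-fold were recovered.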

Other observations

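All tests of explanations in this part were chosen after the results were seen.

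A further group of genes varied strongly between libraries of both groups. By log2(FPKM + 1), 97 tested genes ranged over at least 1.5 within both groups, and 64 of them shared one order of libraries, highest in control library 3 and lowest in control library 1, highest in cold library 1 and lowest in cold library 3. With 36 possible orders, 2.69 genes per order would be expected. The 64 genes took 0.184%, 1.09% and 3.12% of the reads in control libraries 1, 2 and 3, and 1.55%, 0.740% and 0.118% in cold libraries 1, 2 and 3. The 95% Wilson interval of the highest share is 3.11% to 3.13% and that of the lowest 0.117% to 0.120%. Their most abundant member, VIT_201s0010g01260, singled out after its values were seen, stood at 873, 3373 and 9744 FPKM in the control libraries and at 9162, 4097 and 570.04 FPKM in the cold libraries.

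Scaling of whole libraries was argued against for these 64 genes, since the range of the median of all other genes over the libraries of a group was at most 0.0198 of the range of the members' median. A source of fixed composition added in varying amount was left undecided. Among 44 members with 20 or more reads in every library, the ratio to the median member separated cold from control for 59.1%. The 95% Wilson interval, which treats members as independent, is 44.4% to 72.3%. Chance gives 10%, but the groups also did not overlap for 51.4% of all tested genes. Differences between the groups in the leaf's own expression of these genes could give such a share with a fixed source present. Of the members that separated the groups, 9 were relatively higher and 17 relatively lower in cold. Reads from sequence not placed on a chromosome remain a candidate source for part of the group, as 32.8% of the members carry chromosome field 00 against 7.20% of all tested genes (Fisher's exact test, p = 1.8e-09). Organelle-derived or repeated sequence was not tested, and a difference between the plants sampled stays open.

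The runs of consecutive risers could come from a shared response of neighbouring gene copies or from reads of one copy counted on its neighbours. In the latter case the members of a run would keep one profile over the 3 cold libraries. Members were compared if their control level was well below their cold level, and 36 of the 45 runs had at least 2 such members. In 14 of 36 runs the members did not keep one profile. There the chi-square adjusted p was under 0.05. The gap between members, in cold library 3 against the mean of the other cold libraries, was at least 0.5 on the log2 scale (median gap 1.30). When resampled from one profile, 0 of 36 runs gave this. The resampled runs left out the reads that members had in control, which can also make profiles differ. This argues against reads of one copy as the only reads in those 14, but shared reads may still give much of their rise. For the other 22 runs the explanations cannot be told apart: in 16 the members were not shown to differ, and in 6 they differed beyond counting error but by less than the limit of 0.5. Shared regulation was not tested.

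The smaller changes in cold library 3 may have a technical origin, although for genes that fell at least 4-fold cold library 1 deviated about as far the other way (-0.39), so fallers do not set cold library 3 alone apart. Scaling of cold library 3 was argued against, since fallers deviated by 0.18 and risers by -0.18 on the log2 scale, in opposite directions. Admixture of unresponsive leaf would raise strong fallers more than weak ones, and the median deviation was 0.43 for genes that fell at least 4-fold. Risers also deviated more with size, by -0.26 at 8-fold or more, which a weaker or slower response of the plants sampled would give as well. Admixture and such a response cannot be told apart, since both give larger deviations for larger changes.

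Median length differed between the sets as well, and the difference was not tested. The median length implied by the FPKM steps was 1460 bases for genes that rose at least 2-fold, 1615 bases for those that fell and 1962 bases for those not called.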
